A study of Arabidopsis thaliana with 3 samples.

How the data were processed

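Total RNA from wild-type and pistillata inflorescences of Arabidopsis thaliana was compared on cDNA microarrays, per the labels. Each of the 3 deposited samples was a 2-channel comparison with wild-type RNA in channel 1 and pistillata RNA in channel 2, and the titles number them as sets 1 to 3. These sets are called replicates 1 to 3 here. The labels do not say whether the sets came from separate plants, so p-values measure only the spread between these samples, which may be technical. Whether a column came from 1 array or from an average of dye-swapped arrays is not given in the sources used here, and each column is called an array for brevity.

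The deposited values were log ratios that the authors had preprocessed and normalized by the procedure of Wellmer et al., per the labels. The steps of that procedure, the dyes, any dye swap and any filter on dim spots are not given in the sources used here. The log base was taken from the decimals. Multiplied by the natural log of 2, between 98.4% and 98.7% of the values of an array fell within 0.05 of a step of a multiple of 0.0001, against 10% by chance. The same check for log10 gave 9.36% to 10.3%. The values therefore have the form of natural-log ratios kept to a fixed number of decimals and then divided by the natural log of 2. The numerator of the ratio is not given in the sources used here. Signs are reported as deposited, and a group of probes is described as lying on the negative or the positive side of the ratio. Spot intensities were not used here, so neither background nor saturation could be judged, and the precision rests on the number of arrays.

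Each array had 9297 probes with no missing value. No probe ID was found among the gene IDs, locus tags, symbols, synonyms or accessions of the TAIR10.1 gene table, with 0 of 9297 matched, and the deposited table does not pair its IDs with genes. The 14 lists of loci and 1 rule for ribosomal proteins that had been fixed before the data were examined could therefore not be measured, nor could PISTILLATA or its partner APETALA3. The rule for named features, also fixed before the data were examined, then gave the 2 probes with the largest mean log2 ratio on each side, among probes that passed the threshold with 1 sign on all 3 arrays. Each probe was its own feature in every test, as no probes could be averaged to genes. The IDs have the form of a plate number, a row letter and a column number on plates of 8 rows and 12 columns. This reading comes from the form of the IDs, and no label states it.

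The log2 ratios were used as deposited. The mean of each probe over the 3 arrays was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 9297 probes and a threshold of 0.05. The estimated prior had 4.55 degrees of freedom and an SD of 0.255. The fit was tested on 20 simulated sets of 9297 probes and 3 arrays, in which called probes kept their means and 200 of the other probes were given known changes. It called 75.4% of the probes seeded at a log2 size of 0.58, 96.4% at 1 and 100% at 2, and 2.86% of the calls were unchanged probes. The simulated errors were independent, drawn from the estimated prior, and unchanged probes were centred on 0. The share of 2.86% therefore does not cover an offset in the centre of the ratios or errors that probes share. Shares of probes on plates were compared by permuting plates with 100000 resamples. Plates and probes are not biological replicates, and these tests describe the probe set.

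The alternatives fixed before the data were examined were median centring, scaling to 1 median absolute log ratio, robust moderation, array weights, limma's treat against a 1.5-fold change, an unmoderated statistic, a threshold of 0.01, Spearman's correlation and leaving out each replicate. Centring on the mode of each array (density bandwidth 0.05) and adjustment by pin class were added after seeing the data. Figures were drawn with matplotlib 3.10.9.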

Results

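Expression in inflorescences of wild-type Arabidopsis thaliana and of the pistillata mutant was compared by competitive hybridization to cDNA arrays. PISTILLATA encodes a MADS-domain transcription factor that acts with APETALA3 to specify petals and stamens. Mutant flowers form sepals in place of petals and carpelloid organs or no organs in place of stamens. The comparison asks which transcripts differ in abundance between inflorescences with and without normal petals and stamens. The data comprised 3 arrays, each giving 1 log2 ratio between the genotypes for each of 9297 probes. Neither the labels nor the file state which genotype is the numerator, so changes are given by the side of the ratio. The deposited table gives probe IDs without gene names, and the levels of PISTILLATA and APETALA3, which would check the labels, were not analysed here. Counts are of probes, and several probes can come from 1 gene.

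The ratios were strongly asymmetric on every array. On the negative side, 23.9% ± 1.24 (SD, n = 3 arrays) of the probes had a log2 ratio of -1 or lower, a change of at least 2-fold. On the positive side, 0.961% ± 0.457 (SD, n = 3) had a log2 ratio of 1 or higher. The counts on the negative side were 2310, 2258 and 2090 probes on replicates 1, 2 and 3, and those on the positive side were 135, 82 and 51. The array medians lay close to 0, at -0.14, -0.13 and -0.09. The array modes lay above 0, at 0.06, 0.24 and 0.09. The upper quartiles were 0.22, 0.24 and 0.19, whereas the lower quartiles were -0.98, -0.95 and -0.81. The lowest values were -6.30, -5.97 and -10.96, and the highest value on any array was 2.63.

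**Figure D1:**
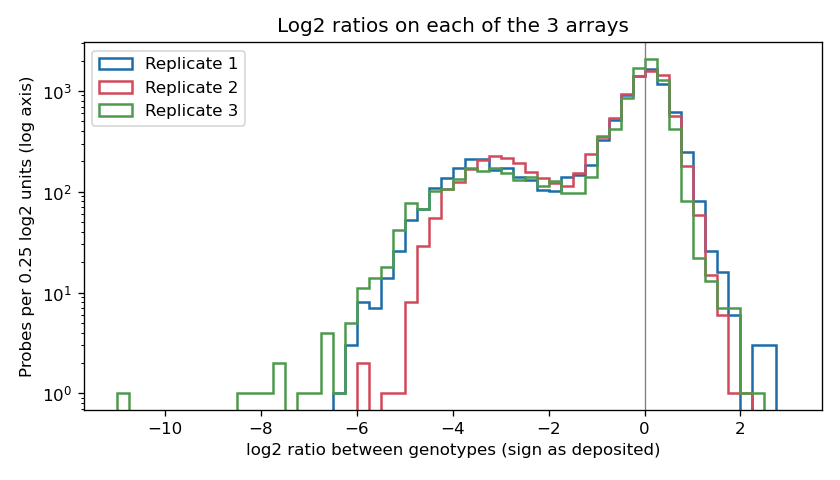
Histogram of the log2 ratios of the 9297 probes (x axis, sign as deposited) with the number of probes in each bin on a log axis (y axis), one line per array. All 3 arrays show a long negative tail, with 2310, 2258 and 2090 probes at -1 or lower, and a short positive one, with 135, 82 and 51 probes at 1 or higher.

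The 3 arrays ran in the same direction. Across probes, which are not independent replicates, Pearson's r was 0.964 between replicates 1 and 2, 0.939 between replicates 1 and 3, and 0.939 between replicates 2 and 3. The large changes carried much of this correlation. Among the 7120 probes with a mean log2 ratio inside ±1, r fell to 0.714, 0.530 and 0.533 for the same pairs. Narrowing the range of the means lowers r by itself, so the fall does not measure how well small changes repeated. The SD of the difference between arrays was 0.404 for replicates 1 and 2, 0.508 for replicates 1 and 3, and 0.501 for replicates 2 and 3. The median SD of a probe over the 3 arrays was 0.231. The sign was shared by all 3 arrays for 6150 probes, or 66.2%, where independent signs would give 25%.

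**Figure D2:**
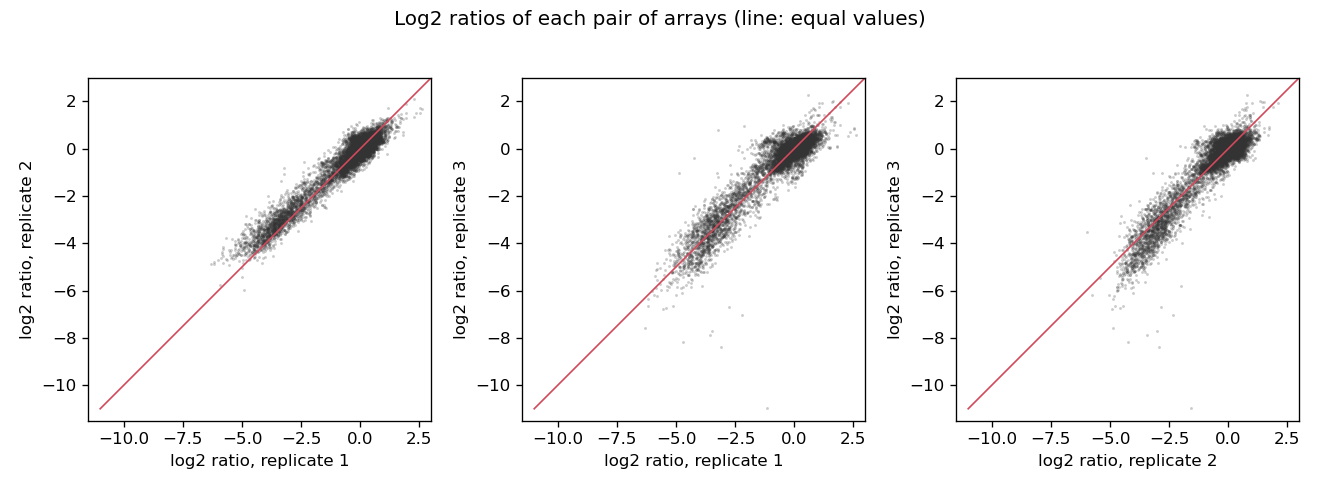
Log2 ratio of each probe on one array (x axis) against another (y axis) for the 3 pairs of arrays, with a line of equal values. Probes of large negative ratio lie along the line in each pair, with r between 0.939 and 0.964, and a few probes fall far below it on replicate 3.

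A total of 3755 probes, or 40.4%, had a mean ratio that differed from 0 by limma's moderated test with an adjusted p under 0.05. Of these, 2963 lay on the negative side and 792 on the positive side. A dye effect shared by the arrays would also pass this test, and the dyes are not given in the sources used here. The negative group was the larger by 3.74 times and also held the larger changes. Its median log2 ratio was -2.39, a 5.24-fold difference, against 0.57, a 1.48-fold difference, for the positive group. The smallest changes that passed were 0.38 on the positive side and -0.38 on the negative side, and 5542 probes did not pass. The size of the positive group depended on the centre of the ratios and on single arrays. It held 1428 probes after median centring, which raised all ratios by 0.12 on average and left 65.5% of the calls on the negative side instead of 78.9%. Median centring moved the array modes, already above 0, further from 0. Centring on the mode instead lowered replicates 1, 2 and 3 by 0.06, 0.24 and 0.09, so replicate 2 moved the most. The positive group then held 377 probes, with 89.9% of the calls negative. It held 268 probes without replicate 1, 265 without replicate 2 and 910 without replicate 3.

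Large changes lay almost entirely on the negative side. With a mean log2 ratio of -1 or lower there were 2126 probes, of which 2122 passed the test, and with 1 or higher there were 51 probes, all of which passed. At a size of at least 2 on the log2 scale, or 4-fold, the negative side held 1665 probes and the positive side 1. At a size of at least 3, or 8-fold, the negative side held 1111 probes and the positive side none. At a size of at least 4, or 16-fold, 357 probes remained, and at 5, or 32-fold, 30 probes. The negative values did not thin out evenly with size. Between -4 and -3 there were 754 probes, more than the 554 between -3 and -2 or the 461 between -2 and -1. On the positive side the counts fell from 313 probes between 0.58 and 1 to 50 between 1 and 2. The spread between arrays tended to grow with size on both sides. The median SD was 0.217 for probes between -0.58 and 0, 0.370 between -4 and -3, and 0.671 at -5 and lower. It was level between -2 and -1 and between -3 and -2, at 0.318 and 0.315. On the positive side the median SD was 0.191 between 0 and 0.58, 0.256 between 0.58 and 1, and 0.372 between 1 and 2.

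The probe with the lowest mean ratio was GP008F9, at -6.25 ± 1.36 (SD, n = 3), a 75.9-fold difference, with an SE of 0.45 and a limma adjusted p of 2.74e-05. Its values on replicates 1, 2 and 3 were -6.30, -4.86 and -7.58. The next was GP100F5, at -5.95 ± 0.21 (SD, n = 3), a 61.8-fold difference, with a limma adjusted p of 3.55e-06. The probe with the highest mean ratio was GP032C8, at 2.11 ± 0.16 (SD, n = 3), with a limma adjusted p of 1.40e-05. GP079D10 followed at 1.86 ± 0.10 (SD, n = 3), a 3.64-fold difference, with a limma adjusted p of 2.03e-05. The difference between GP008F9 and GP100F5 was smaller than the SD of GP008F9. The mean of GP008F9 was -6.94, or 123-fold, without replicate 2 and -5.58, or 47.8-fold, without replicate 3. GP008F9 lies in row F of plate 8, and 5 other probes in row F of plates 4 to 11 read more than 2 log2 units lower on replicate 3 than on the mean of the other arrays. Without replicate 3, GP100F5 was the lower of these probes, at -5.84.

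The changed probes were unevenly spread over the probe set. Read as plate positions, the IDs covered 114 plates in 4 runs of plate numbers. In the run from 0 to 11, 15.3% ± 1.48 (SD, n = 3 arrays) of 742 probes had a log2 ratio of -1 or lower. The share was 5.40% ± 1.75 (SD, n = 3) of 216 probes on plates 32 to 35. It was 25.3% ± 1.27 (SD, n = 3) of 405 probes on plates 41 to 45, and 25.1% ± 1.22 (SD, n = 3) of 7934 probes on plates 55 to 147. The shares per plate differed between the 4 runs (permutation test over 114 plates, two-sided by construction, p = 0.00181, adjusted p = 0.00181 over 2 comparisons). This test takes plates as exchangeable, but neighbouring plates of the last run were alike, as described below. Its p-value may therefore be too small. The share at 1 or higher was 2.61% ± 0.823 (SD, n = 3) on plates 0 to 11, against 0.752% ± 0.424 (SD, n = 3) on plates 55 to 147.

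Within the last run the probes fell into 2 parts, a split chosen after the values were seen. On plates 55 to 118, 33.0% ± 1.49 (SD, n = 3 arrays) of 5661 probes had a log2 ratio of -1 or lower. On plates 119 to 147 the share was 5.50% ± 0.595 (SD, n = 3) of 2273 probes. No plate of the first part overlapped any plate of the second. The mean log2 ratio was -1 or lower for 20.2% to 44.6% of the probes of each of the 64 plates of the first part, and for 1.25% to 10.1% on each of the 29 plates of the second. The plate shares differed by 26.5 percentage points on average (permutation test over 93 plates that takes the best split of each resample, two-sided, p = 1e-05, the smallest that the resamples can give, adjusted p = 2e-05). The first part held 2399 of the 2963 called negative probes. Of its probes, 42.4% were called negative and 5.88% positive. In the second part, 9.55% were called negative and 12.1% positive. A mean log2 ratio of -3 or lower was found for 17.0% of the probes of plates 55 to 118 and for 1.80% of those of plates 119 to 147.

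**Figure D3:**
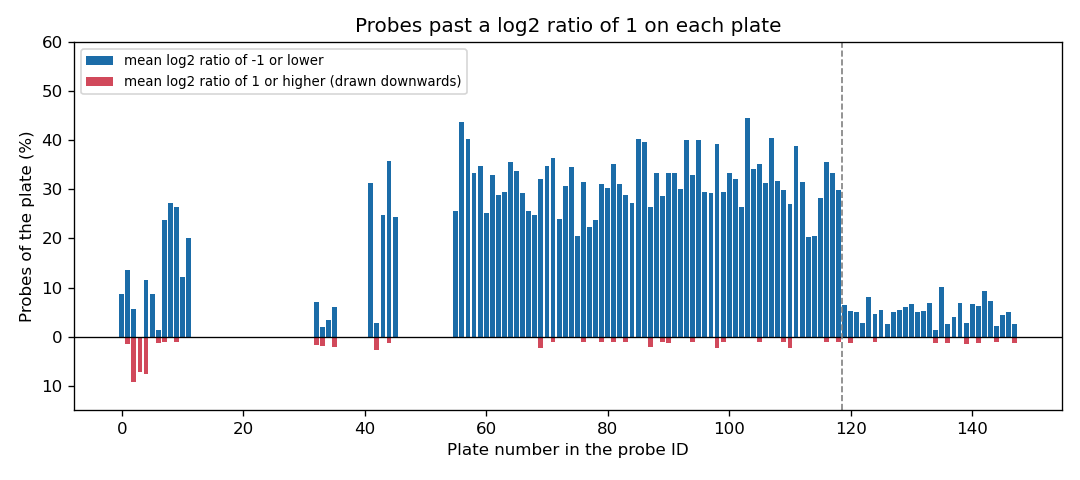
Share of the probes of each plate (y axis, percent) with a mean log2 ratio of -1 or lower (blue, upwards) or of 1 or higher (red, downwards), by the plate number in the probe ID (x axis). The dashed line marks the end of plates 55 to 118, where 20.2% to 44.6% of the probes lie at -1 or lower, against 1.25% to 10.1% on plates 119 to 147.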

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

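Calls on the negative side outnumbered those on the positive side under every alternative run, but the ratio moved from 3.74 to 1.90 after median centring and to 8.94 after mode centring, and was 3.51 to 9.94 without 1 replicate, 10.6 at an adjusted p under 0.01 and 66.5 under treat. The main count of 3755 probes fell to 2094 when a change of over 1.5-fold was tested with treat, and to 2102 with an unmoderated statistic per probe. The negative side, 2963 probes, fell to 1891 with the unmoderated statistic. The positive side, 792 probes, moved the most as a proportion. It held 1428 probes after median centring, 377 after mode centring, 31 under treat, 211 with the unmoderated statistic and 237 at an adjusted p under 0.01. Leaving out 1 replicate gave 2786 to 4101 probes in all, 265 to 910 on the positive side and 2521 to 3191 on the negative side. Of the 3755 calls, 73.8% were kept without replicate 2 and 94.1% without replicate 3. The mean correlation between arrays was 0.947, was 0.800 as Spearman's rho, and ranged from 0.939 to 0.964 without 1 replicate. The 4 named probes passed the threshold under each of the 9 refits, and GP008F9 ranged from -6.94 to -5.58 without 1 replicate. The causes were not tested beyond what each setting removes. Averaging probes of a gene, the gene lists and the mutated gene could not be run without gene names, and the setting for missing values had none to act on. The main test is itself paired, as each ratio sets both genotypes against each other on 1 array.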

Other observations

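All tests in this part were chosen after the values were seen.

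The first pattern is the asymmetry, with 41.7 times as many probes at a mean log2 ratio of -1 or lower as at 1 or higher. An offset of the size of the array medians does not account for the asymmetry. Median centring, which moves the ratios against the pattern by 0.09 to 0.14, left a ratio of 22.0, with 9.37 to 28.4 on single arrays. A shift of 0.50 to 0.59 would be needed to bring an array under 2. Median centring could not test an offset of that size, and centring on the mode moves the ratios the other way. The probes of plates 55 to 118 do not account for all of the asymmetry either. The ratio was 11.2 on the other plates, with 5.22 to 9.67 on single arrays. A dye effect shared by the arrays stays open, as the labels give no dyes and it would also give correlations between arrays such as the lowest of 0.939. Turning the sign of whole arrays gave 4 patterns, too few for a share under 0.05. The real pattern called 3755 probes and the highest of the others called 0, so 1 of the 4 gave a count as large.

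The direction of the ratio is a hypothesis of its own. A larger negative side is what a ratio of pistillata over wild-type may give, since the mutant lacks petals and stamens and the transcripts particular to them. The imbalance of 41.7 does not decide this on its own. Transcripts of the organs formed instead would lie on the other side, and how many there are and how far they change is not known here. The sizes were one-sided too, with 1111 probes at a mean log2 ratio of -3 or lower and none at 3 or higher. The labels name neither the dyes nor the numerator, so the direction stays a hypothesis.

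The second pattern is the step between plates 118 and 119, which was the best single split of plates 55 to 147. A deviation of 1 array was argued against, since the share of probes at -1 or lower was at least 5.57 times as large on plates 55 to 118 on every array. A shift of all ratios of those plates was argued against too. After every plate was set to the same upper quartile, the shares were 30.8% and 5.90%, and the ratio was at least 4.76 on every array. Other differences between these plates that all arrays share were not tested, and spot intensities were not used here. Also open is the content of the clones, such as separate clone collections or many clones of the same transcripts in one of them. In the latter case the count of probes would overstate the number of genes. Testing the content of the clones needs gene names for the probes, which were not used here. Plate 42 stood apart from its neighbours in the same way, with 2.82% of its probes at -1 or lower, against 24.4% to 35.8% on plates 41, 43, 44 and 45.

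The third pattern is in the deviations of each array from the mean of the probe. On replicate 2 the mean deviation was 0.13 in row D and 0.12 in row H, and between -0.01 and 0.04 in the other rows. On replicate 1 it was -0.11, -0.08 and -0.12 in columns 1, 5 and 9, and between -0.02 and 0.00 in the other columns. A candidate explanation is a pin effect left after the authors' normalization, since both series repeat every 4 wells, as the pins of a 4 by 4 print head would. In the 5192 probes outside those rows and columns, the classes of such a head explained 0.686% of the sum of squares of the deviations, and 19 of 1000 random groupings into classes of the same sizes explained as much. The class means over all wells ran from -0.16 to 0.17, near the size of the median SE of 0.143, and 97.9% of the calls were kept after adjusting for the classes.

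On replicate 3, 8 probes lay more than 2 log2 units below the mean of the other arrays and 6 lay more than 2 above it. Of the 8, 5 were in row F of plates 4 to 11, a row with 13.0% of all probes. The row and the range of plates were picked after these values were seen. GP004F5 and GP004F6, both among the 5, lie in neighbouring wells, so the 5 may not be independent. These 5 read from -8.38 to -6.68 on replicate 3, against -3.56 to -2.22 on replicate 1 and -3.45 to -2.32 on replicate 2. GP008F9, in the same row of plate 8, was also lowest on replicate 3, at -7.58 against -6.30 and -4.86, just inside the limit of 2. In row D of plate 2, the 4 probes picked for reading above 2 on replicate 1 read from 2.38 to 2.63 on replicate 1, from 1.51 to 1.72 on replicate 2 and from 0.59 to 0.89 on replicate 3. The 7 other probes of that row read from -1.55 to 0.36 on replicate 1 and from -1.49 to 0.97 on replicate 3.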
